A study of Mus musculus with 7 samples.

How the data were processed

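Gene expression was measured by RNA sequencing in 7 mouse libraries. Per the labels' protocols, tdTomato-positive cells (and tdTomato-negative cells for 1 group) were obtained after collagenase and dispase digestion of the small bowel muscle layer with its myenteric plexus, or of posterior subcutaneous fat pads. They were cultured in a proliferation medium with basic fibroblast growth factor, epidermal growth factor and heparin. RNA of about 50000 cells per group, pooled equally from 3 mice, was extracted with Trizol, amplified as full-length cDNA with the SMART-Seq v4 kit and made into libraries with Nextera XT. Amplified reads without molecular identifiers are not independent molecules.

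The values are CPM (read counts scaled to the library total) per Entrez gene, as deposited by the authors for each library. Per the submitters' processing notes, bcl2fastq 2.17, HISAT and featureCounts were used with the mm10 genome; the settings and annotation used, and the versions of HISAT and featureCounts, are not given in the sources used here. All values of a library were whole multiples of the CPM of 1 read, so whole reads were recovered from the deposited CPM; 100% of values came out whole within 0.05 read. Totals ranged from 51885106 to 65301500 reads per library. 3 reads, the floor used for genes with 0 reads, correspond to between 0.0459 and 0.0578 CPM. Symbols and coordinates were taken from a RefSeq table of GRCm38, the assembly behind mm10, by Entrez identifier. 25275 of 27179 identifiers matched, and the 1904 others held between 0.222% and 0.351% of the reads of a library. Near-identical gene copies can share or lose reads, and strand use in counting is not given in the sources used here, so overlapping genes are uncertain too.

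Groups were taken from the labels, with 1 library each, so no residual degrees of freedom remain and no count test could be run on the recovered reads; no p-values or standard errors are given. Libraries were scaled by TMM over all 7 libraries (edgeR 4.0.16 in R 4.3.3) using the 16461 genes with at least 1 CPM in a library. Log2 ratios were computed from scaled reads with a prior count of 2, which understates the ratios of low genes. A gene was measured in a comparison at 1 CPM or more in either library. It passed the size rule at 4-fold or more with a 95% exact conditional binomial counting interval of the ratio wholly beyond 2-fold. CPM printed beside genes are plain CPM. Ratios against 0 reads are given as bounds from the floor of 3 reads, and ratios of genes with 1 to 3 reads are given with their interval.

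9 comparisons, the size rule, 29 gene lists (pan-neuronal and neuronal subtype, neural crest, glial, myelin, other cell types, Hox groups, stress, growth and metabolic genes, Xist with Y-linked genes) and the alternatives listed here were chosen before the data were examined. Of 394 list members, 393 were found. A list's median log2 ratio was placed among those of 10000 random lists of the same size, drawn from 20 bins of mean expression, where at least 4 members were measured. Named genes were the 10 with the highest and the 10 with the lowest log2 ratio of a comparison (5 and 5 in the last 4 comparisons) among genes that passed with at least 10 CPM in the higher library, without unnamed gene models and the Xist and Y-linked list. Members of the fixed lists were named as well. Genes outside this rule (the most abundant gene of a library, those picked for the plot of marker levels, and the lists of acinar, mature dendritic and immature neuron genes) were chosen after the data were examined. Some genes that the rule names are not reported here.

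The steps were tested on simulated reads for the spheroid sort comparison, with 13507 genes measured. Both simulated libraries were drawn from a shared profile with counting noise only. The test therefore checks the steps and does not give a rate of false calls for real single libraries. Of 50 genes raised 8-fold and 50 lowered 8-fold, all were called. Of 50 raised and 50 lowered 3-fold, 0 were called, as were 0 of 13307 unchanged genes. 5 of 100 unchanged lists of 12 genes lay outside the central 95% of random lists. The alternatives were scaling by total counts or by DESeq2 1.42.0 size factors, no filter or a filter at 5 CPM, a prior count of 0.5, rules of 2-fold and 8-fold, and M1 neurospheres or tdTomato-positive spheroid cells as the bowel library of the neurosphere tissue comparison. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. No library was left out.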

Results

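RNA sequencing was carried out on neural crest-derived cells of the mouse small bowel and subcutaneous fat, before and after culture as neurospheres. In Wnt1-tdT mice, Cre recombinase under the Wnt1 promoter switches on the red fluorescent protein tdTomato in neural crest cells and their descendants, so that these cells can be collected by fluorescence-activated sorting. The 7 libraries came from 7 groups with 1 library each. For adipose tissue they were freshly sorted (primary) cells and neurospheres grown in 2 stages. For the bowel they were primary cells, neurospheres from cells sorted before 10 days of culture (method M1), the tdTomato-positive and tdTomato-negative cells of mixed spheroids sorted after 10 days, and neurospheres grown for 10 further days from such sorted positive cells (method M2). Each library was made from a pool of 3 mice aged 1 month, 2 of them female and 1 male.

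The libraries held between 51885106 and 65301500 reads assigned to genes. Between 12401 and 14690 genes reached 1 CPM (read count scaled to the library total) in a library. With 1 library per group, no difference reported here has a replicate check, and the intervals given cover counting error only. A gene is called higher or lower where it passed a size rule, which asked for a 4-fold difference with a counting interval wholly beyond 2-fold. Under a 2-fold rule more genes passed in each of the 9 comparisons, between 2647 and 7426. Percentiles place the median of a gene list among 10000 random lists of the same size and similar expression, as a description of these libraries. Medians with members at 0 reads held at their bound (a floor of 3 reads) were the same unless given. Across genes, which are not independent replicates, log2 CPM of the M2 neurospheres correlated with that of the tdTomato-positive spheroid cells at a Pearson r of 0.952, and that of both primary libraries with each other at 0.741. In adipose primary cells, Sparc was the most abundant gene with 10030 CPM, and in bowel primary cells it was Cela2a, a pancreatic elastase, with 15480 CPM.

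**Figure D1:**
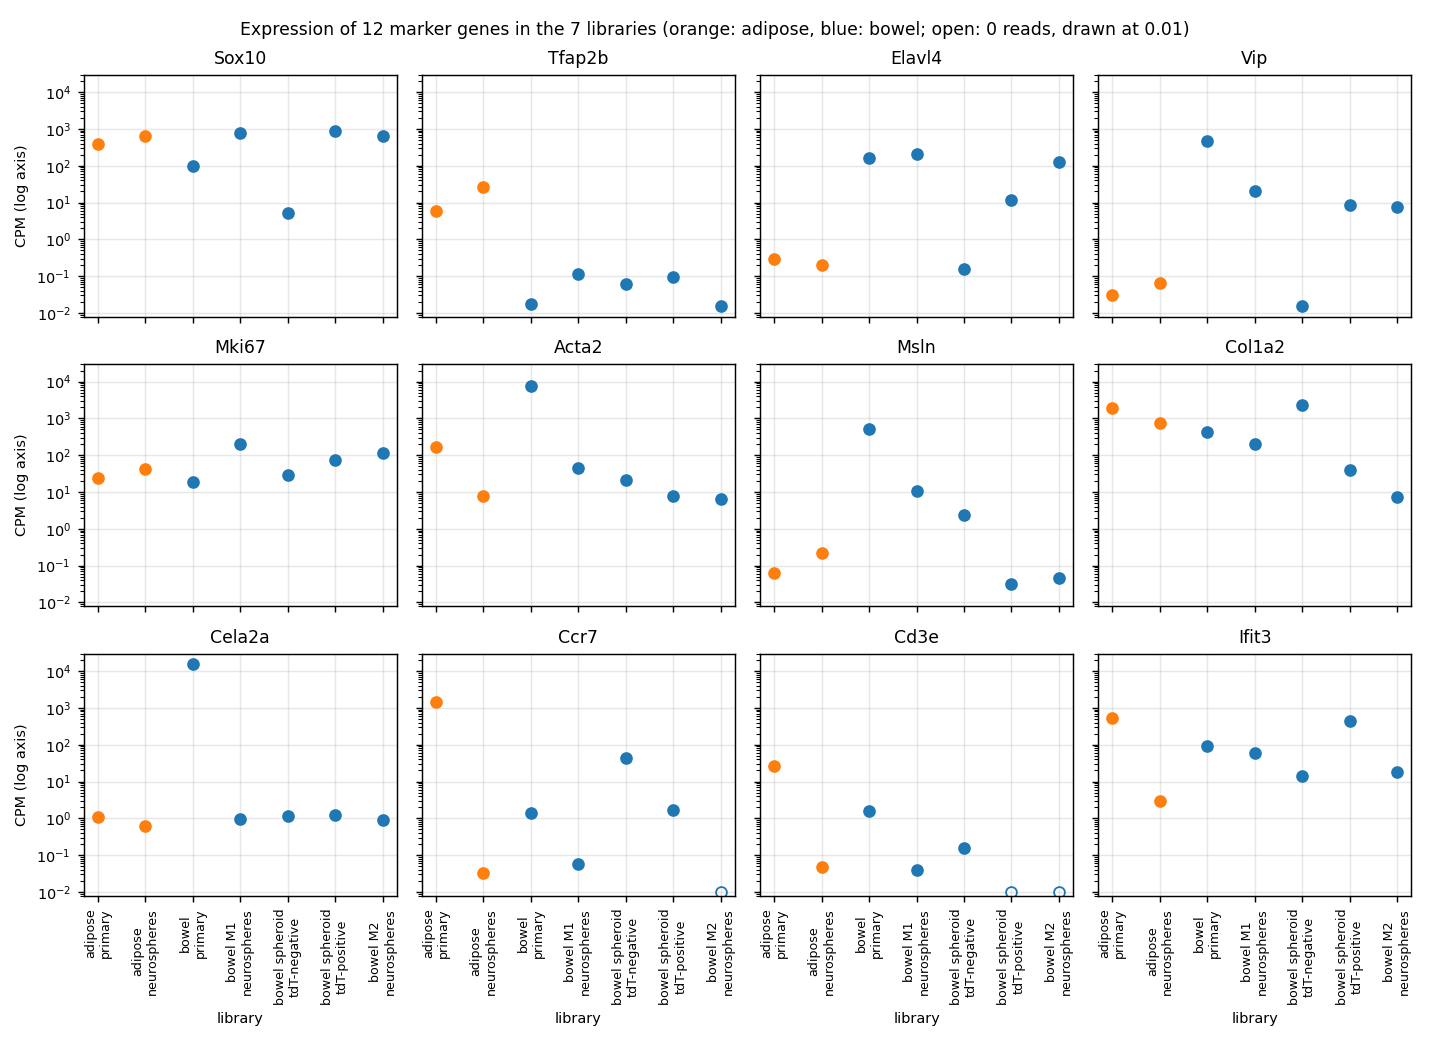
CPM on a log axis of 12 genes, chosen after their values were seen, in each of the 7 libraries; each point is 1 library, and open points mark 0 reads. Sox10 lay at 5.23 CPM in the tdTomato-negative cells and between 98 and 899.6 CPM in the other libraries.

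To see which transcripts set neural crest-derived cells apart from the other cells of the same bowel spheroids, the tdTomato-positive library was compared with the tdTomato-negative one. Sox10, the transcription factor that maintains crest progenitors and glia (Entrez 20665; chromosome 15, 79154913 to 79164490, GRCm38), had 899.6 against 5.23 CPM (log2 ratio 7.18, 95% counting interval 7.03 to 7.34). All 15 measured glial genes were higher (median log2 ratio 6.05, percentile 100), among them the calcium-binding protein S100b with 276 against 2.21 CPM and the receptor Gpr37l1 with 384 against 1.07 CPM. Matrix genes went the other way, with 13 of 16 fibroblast and matrix genes lower (median log2 ratio -4.77, percentile 0). Dcn, which encodes decorin, had 157 against 7124 CPM, and Pdgfra, a receptor of mesenchymal cells, had 6.14 against 576 CPM.

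Of the neural crest and enteric progenitor genes, 10 of 15 were higher (median log2 ratio 3.16, percentile 100). They included Erbb3 (log2 ratio 7.12), Ngfr (7.28) and Foxd3 (8.46). Phox2a was the 1 lower member (-5.24), and Ret (0.57) and Hand2 (-0.32) passed in neither direction. 9 of 11 pan-neuronal genes were higher (median log2 ratio 5.21, or 4.79 with members at 0 reads held at their bound, percentile 100), including Gap43 (7.69) and Elavl4 (5.74), while Snap25 was lower (-4.78). Neurotransmitter and subtype genes were split, with 5 of 14 higher, such as Vip and Cartpt, and 7 lower, such as Slc17a6 and Slc5a7 (median log2 ratio -1.98, percentile 2.68). Vip, a neuropeptide of inhibitory motor neurons, had 8.71 against 0.0155 CPM (log2 ratio 7.41, 95% counting interval 6.41 to 14.20). 6 of 12 Schwann cell myelin genes were higher and 2 lower (median log2 ratio 2.51, percentile 100), with Dhh at 5.77 and Mbp at 4.07. 6 of 14 Notch pathway genes were higher and 3 lower (median log2 ratio 1.36, percentile 100), with the ligand Dll3 and the receptor Notch1 (3.90) among the higher genes and Notch2 (-2.29) and Notch3 (-3.57) among the lower ones. 4 of 15 interferon response genes were higher and 1, Ifi44, was lower (median log2 ratio 1.53, percentile 100), with Ifit3 at 4.69. None of the 28 proliferation genes passed the size rule (median log2 ratio 0.97, percentile 100).

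Besides the fibroblast genes, the tdTomato-negative library held higher levels of 5 of 5 mesothelial genes (median log2 ratio -5.33, percentile 1.02), 5 of 6 interstitial cell of Cajal genes (median log2 ratio -4.39, percentile 0.02), 6 of 8 Hox genes of groups 6 to 9 (median log2 ratio -3.02, percentile 0.77) and 8 of 11 endothelial genes (median log2 ratio -2.58, percentile 5.17). Thbs4 reached 3939 CPM in that library against 29.1 CPM in the positive cells, and fibronectin (Fn1) was its most abundant gene with 22970 CPM. 5 of 11 smooth muscle genes were lower in the positive cells (median log2 ratio -1.87, percentile 0.125), 4 of 5 mast cell genes (median log2 ratio -5.33, or -4.81 with members at 0 reads held at their bound, percentile 0.675), 4 of 6 adipocyte genes (median log2 ratio -3.86, percentile 0.32) and 5 of 16 hypoxia and glycolysis genes (median log2 ratio -1.15, percentile 0.01). Among macrophage genes 1 of 12 was lower, Lyz2 (-2.26). Of the 10 genes with the highest ratios, Wfdc18, Cmtm5, the gap junction gene Gjc3, Foxd3 and Sox2 had log2 ratios of 9.62, 8.88, 8.49, 8.46 and 8.24. Vmn1r181, Lsamp, Dlgap2 and Csmd2 had 0 reads in the negative library, which made them at least 300-fold, 247-fold, 210-fold and 183-fold higher, respectively; Myh14 had 1 read there (log2 ratio 8.29, 95% counting interval 7.30 to 15.09). Of the 10 lowest, Ccbe1 (-8.63), Ggt5 (-8.52), Igf2 (-7.85), Gprin3 (-7.76), Galnt14 (-7.71) and Akr1c18 (-7.70) had reads in both libraries. Slc35d3 and the immunoglobulin segment Iglv1 had 0 reads in the positive cells and were at least 275-fold and 329-fold lower, respectively, while Tll2 (-8.59, interval -12.68 to -7.78) and Iglc1 (-8.53, interval -15.48 to -7.70) had 1 or 2 reads; reads of immunoglobulin segments can be shared between copies. In all, 927 genes were higher and 1737 lower among 13951 measured.

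The tissue of origin was first compared in freshly sorted cells, adipose against bowel. Bowel cells had the neuronal transcripts: 17 of 18 pan-neuronal genes (median log2 ratio -6.11, percentile 0) and 23 of 24 neurotransmitter and subtype genes (median log2 ratio -8.04, or -7.76 with members at 0 reads held at their bound, percentile 0) were lower in adipose cells. Elavl4, an RNA-binding protein of neurons (Entrez 15572; chromosome 4, 110203737 to 110351939, GRCm38), had 0.297 against 162 CPM (log2 ratio -8.97, 95% counting interval -9.84 to -8.47). Adipose cells had the myelin transcripts, with 13 of 15 Schwann cell myelin genes higher and 1, Mpzl2, lower (median log2 ratio 3.0, percentile 100). Mbp, the myelin basic protein (chromosome 18, 82475091 to 82585637), had 2093 against 287 CPM (log2 ratio 2.85, 95% counting interval 2.82 to 2.87), and Prx had 53.2 against 1.56 CPM. Both libraries also held transcripts of other cell types, lymphocyte genes in adipose cells and smooth muscle, mesothelial and digestive enzyme genes in bowel cells.

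Galanin (Gal) had 9.96 against 2079 CPM, Cartpt had 0.203 against 199.7 CPM, and the nicotinic receptor subunit Chrna3 had 0.344 against 156 CPM. The pan-neuronal gene that passed in neither direction was Map2 (log2 ratio -1.0). Within the neural crest and enteric progenitor genes 4 were higher in adipose cells and 6 lower, of 17 (median log2 ratio -0.27, percentile 14.4). Pax3 (chromosome 1, 78101267 to 78197136) had 15.4 against 0.0347 CPM (log2 ratio 7.90, 95% counting interval 6.92 to 11.83), Tfap2b had 5.7 against 0.0173 CPM (log2 ratio 6.92, 95% counting interval 5.86 to 13.65), and Erbb3 (2.33) and Tfap2a (2.69) were higher too. Ret, the receptor for glial cell line-derived neurotrophic factor, had 1.51 against 55.7 CPM, and Hand2 had 0.0937 against 19.2 CPM. Sox10 had 377 against 98 CPM and did not pass (log2 ratio 1.93, 95% counting interval 1.88 to 1.97). Of 16 glial genes 5 were higher and 2 lower (median log2 ratio 1.22, percentile 100), with Gfra3 at 2836 against 34.7 CPM and Gfap at 13.1 against 65.6 CPM. Hox genes of groups 1 to 5 were lower in 10 of 12 (median log2 ratio -4.41, percentile 0.01), led by Hoxb5 with 0.0469 against 71.5 CPM (log2 ratio -9.89, 95% counting interval -12.87 to -9.05) and Hoxa5 with 1.37 against 94.4 CPM, and so were 5 of 7 of groups 6 to 9 (median log2 ratio -3.0, percentile 0.84). Both measured Hox genes of groups 10 to 13 were higher, Hoxa10 and Hoxc10, at 2.45 and 1.47 CPM in adipose cells and 0 reads in bowel cells.

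Markers of other cell types differed as well. In adipose cells 11 of 12 lymphocyte genes were higher (median log2 ratio 4.61, percentile 100), such as Cd3e with 27.2 against 1.56 CPM and Cd79a with 70.6 against 1.58 CPM. None of 13 macrophage genes (median log2 ratio -1.31, percentile 0) and none of 11 endothelial genes passed (median log2 ratio -0.026, percentile 26.1). Bowel cells had all 12 smooth muscle genes (median log2 ratio -6.24, percentile 0) and all 7 mesothelial genes (median log2 ratio -10.1, percentile 0) at higher levels, with Myh11 at 2901 and Msln at 527 CPM. 6 of 10 epithelial genes were lower in adipose cells (median log2 ratio -2.56, percentile 0.1), as were 3 of 7 interstitial cell of Cajal genes (median log2 ratio -1.97, percentile 0.41) and 3 of 7 skeletal muscle genes (median log2 ratio -1.39, percentile 7.21). The 10 lowest genes were digestive enzymes of the pancreas and related secreted proteins (Pnliprp1, Clps, Rnase1, Ctrb1, Reg3b, Cel, Try5, Try4, Pnlip and Prss2). Cel had 0.359 against 6994 CPM and Clps had 0.141 against 4802 CPM; Reg3b, with 0 reads in adipose cells, was at least 13100-fold lower, and Pnliprp1, with 3 reads there, had a log2 ratio of -15.24, interval -18.23 to -14.40. Counts of Try4, Try5 and Prss2 are uncertain, since reads can be shared among trypsin copies. A list of 25 acinar genes, written after these values were seen, took 9.12% of the reads of the bowel primary library and at most 0.0247% in each other library.

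The 10 highest genes included Ccr7, Fcer2a, Fcmr and Blk, known from lymphocytes and dendritic cells, and Ngp and S100a8, known from neutrophils. The chemokine receptor Ccr7 had 1473 against 1.39 CPM (log2 ratio 10.00, 95% counting interval 9.72 to 10.37), and Apol7c had 1688 against 0.451 CPM. The histocompatibility gene H2-M2 had 1623 CPM in adipose cells and 0 reads in bowel cells (at least 30800-fold higher). Ngp, Fcer2a, Calm4, Spata31d1b and Blk also had 0 reads in bowel cells and were at least 944-fold, 937-fold, 315-fold, 226-fold and 224-fold higher, respectively, while Fcmr (8.91, interval 8.06 to 11.30) and S100a8 (9.17, interval 8.27 to 12.09) had 3 or 4 reads there. 4 of 15 interferon response genes (median log2 ratio 1.82, percentile 100), 3 of 15 immediate early and stress genes (median log2 ratio 1.59, percentile 100) and 3 of 12 FGF and EGF response genes (median log2 ratio 1.28, percentile 100) were higher in adipose cells, and none was lower. Mx1 led the interferon genes with 86.3 against 2.76 CPM; Hspa1a (3.14) and Hspa1b (3.11), near-identical copies that can share reads, and Egr1 (2.02) were the higher stress genes. 4 fibroblast and matrix genes were higher and 1 lower of 16 (median log2 ratio 0.63, percentile 98.7), and adipocyte genes were 1 higher and 2 lower of 12 (median log2 ratio -0.28, percentile 13.5). Mast cell (median log2 ratio 0.58, percentile 85.8), melanocyte (median log2 ratio 0.36, percentile 70.6) and erythroid genes (median log2 ratio -1.11, percentile 0.49) had 0, 1 and 0 higher members and no lower ones. In all, 1107 genes were higher and 1775 lower among 15585. Over genes at CPM 1 in a cultured tdTomato-positive library, a choice made after seeing the data, the count was 1808 in place of 2882, and at CPM 5 it was 1909.

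The tissue comparison was repeated after culture, with adipose neurospheres set against bowel M2 neurospheres, both grown in 2 stages. Gal still parted the tissues with 0.195 against 328 CPM (log2 ratio -10.37, 95% counting interval -11.55 to -9.79), and Ret had 1.3 against 274 CPM (log2 ratio -7.57, 95% counting interval -7.94 to -7.28). Hand2 had 0.162 against 73.2 CPM, and the serotonin receptor subunit Htr3a had 0.0974 against 228 CPM. On the adipose side stood Tfap2b (chromosome 1, 19208908 to 19238845), with 26.7 against 0.0153 CPM (log2 ratio 9.15, 95% counting interval 8.41 to 16.19), and Pax3, with 20.1 against 0.0766 CPM. The crest regulators Sox10 (632 against 661 CPM; log2 ratio 0.056) and Foxd3 (81.3 against 90.1 CPM; -0.028) passed in neither direction.

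9 of 13 pan-neuronal genes (median log2 ratio -3.87, percentile 0) and 9 of 13 neurotransmitter and subtype genes (median log2 ratio -3.86, percentile 0.14) were lower in adipose neurospheres. Elavl4 (-8.98), Syt1 (-7.38) and Chrna3 (-8.42) were among them, whereas Uchl1 (2.38) and Gad2 (5.67), the enzyme that makes the transmitter GABA, were higher. Of the 16 measured crest and progenitor genes, 3 were higher and 5 lower (median log2 ratio 0.014, percentile 48.5), with Ret, Hand2 and Sox8 among the lower genes. Glial genes were 7 lower and 3 higher of 15 (median log2 ratio -0.41, percentile 1.56): Gfap had 1.35 against 874 CPM and Gpr37l1 had 1.12 against 453 CPM, while Col28a1 had 296 against 12.8 CPM. Myelin genes were 2 higher and 3 lower of 11 (median log2 ratio -0.51, percentile 13.2), the lower ones being Pmp22 (-5.98), Mbp (-3.77) and Pou3f1 (-3.63). 7 of 12 Hox genes of groups 1 to 5 were lower (median log2 ratio -2.73, percentile 0.06), with Hoxa5 at -6.07 and Hoxd3 at -5.11. Hox genes of groups 6 to 9 had 3 higher members, Hoxa9, Hoxb9 and Hoxd9, and 1 lower, Hoxb6, of 7 (median log2 ratio 1.63, percentile 98.8). Hoxa10, the 1 measured gene of groups 10 to 13, was higher with 1.1 against 0.0153 CPM (log2 ratio 4.60, 95% counting interval 3.77 to 11.62).

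6 of 15 fibroblast and matrix genes were higher in adipose neurospheres (median log2 ratio 1.44, percentile 100), led by Col1a2 with 770.2 against 7.52 CPM, and Fbln1 was lower (-6.41). That median was -0.31 with M1 neurospheres as the bowel library. Interstitial cell of Cajal genes had 1 higher member, Ano1 (7.49), and 1 lower, Etv1 (-3.88), of 4 (median log2 ratio 1.42, percentile 98.7), and their median was -2.68 against M1. 2 of 20 cholesterol synthesis genes were lower, among them Stard4 (median log2 ratio -1.03, percentile 0). 6 of 16 hypoxia and glycolysis genes were lower and 2 higher (median log2 ratio -0.88, percentile 0.04), with Pdk1 at -4.46 and Bnip3 at -2.33; against M1 this median was 0.095. 3 of 15 immediate early genes were lower (median log2 ratio -0.58, percentile 0.31), and none of 28 proliferation genes passed (median log2 ratio -0.33, percentile 0.3); these medians were 0.061 against M1 and 0.0081 against the tdTomato-positive spheroid cells, respectively. 3 of 11 interferon response genes were lower (median log2 ratio -0.67, percentile 6.38). Notch pathway genes were 1 higher and 3 lower of 13 (median log2 ratio 0.29, percentile 84.4), the higher one being the ligand Jag1 with 995 against 28.9 CPM.

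Genes with 0 reads in M2 neurospheres were among the 10 highest, such as the transporter Slc16a11 (at least 5470-fold higher), the cartilage proteoglycan aggrecan (Acan; at least 1370-fold higher) and the osteoblast factor Sp7 (at least 516-fold higher). Prl2c2 (11.07) and Prl2c3 (10.11), prolactin family copies that can share reads, Crabp2 (9.04), Asgr1 (9.30) and Cdh15 (9.82, interval 9.08 to 13.98) followed. Besides Gal and Htr3a, the 10 lowest included C4b (-11.04), Gpc3 (-10.00), Sstr1 (-10.62, interval -14.68 to -9.78), Tmem255b (-10.01, interval -16.91 to -9.13), Spock3 (-9.97, interval -14.02 to -9.12), Kcne1l (at least 1230-fold lower) and Pcsk6 (at least 1050-fold lower). In all, 716 genes were higher and 1168 lower among 13440; at CPM 5 the count was 1216 in place of 1884. With M1 neurospheres as the bowel library the split was 555 higher and 2001 lower, and with tdTomato-positive spheroid cells 474 and 1097. Of the 716 higher and 1168 lower genes, 387 and 947 passed alike against M1, and 6 passed in the opposite direction. Against the spheroid cells these were 387, 649 and 1. Only 252 higher and 555 lower genes passed alike against both, so many calls depended on the bowel library used. The primary and neurosphere ratios, from 4 separate libraries, correlated across 12958 genes at a Pearson r of 0.22 and a Spearman rho of 0.0831; genes are not independent replicates. 87 genes were higher in both comparisons, where independent lists would share 21.6, and 392 were lower in both, where they would share 78.6. A further 198 genes passed in opposite directions, where independent lists would give 82.5.

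**Figure D2:**
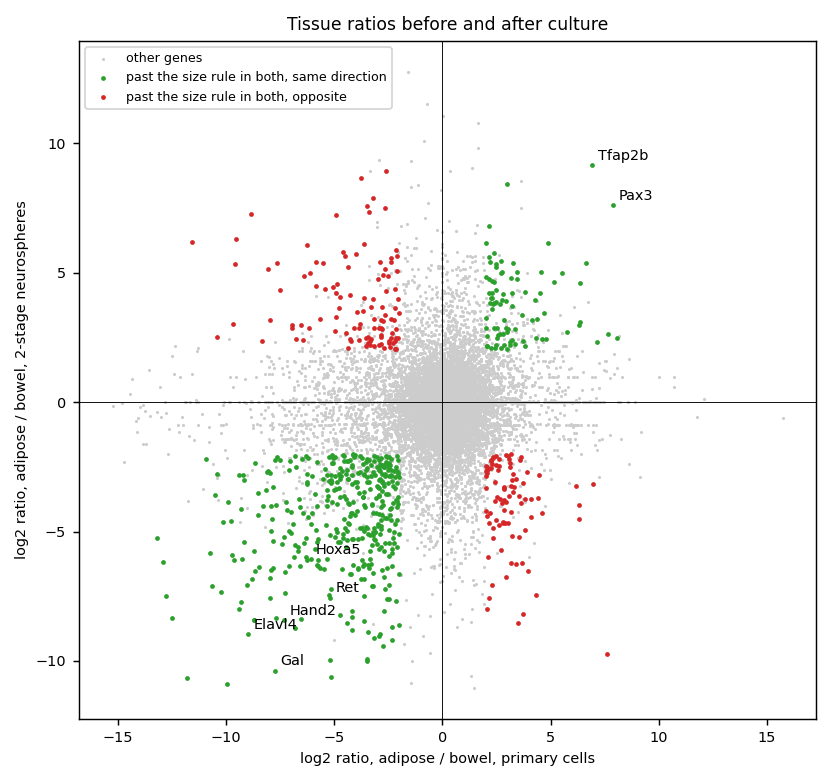
Log2 ratio of adipose to bowel in primary cells (x axis) and in 2-stage neurospheres (y axis), each point a gene; green marks genes that passed the size rule in the same direction in both, red in opposite directions. Gal lay at -7.72 and -10.37, on the bowel side of both comparisons, and Tfap2b and Pax3 lay on the adipose side.

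How cultured bowel cells differed from fresh ones was examined first in M1 neurospheres, grown for 10 days from sorted cells, against primary cells. Markers of other cell types were lower in culture too. A changed mix of cells therefore cannot be told apart from changes within crest-derived cells. Cell cycle transcripts were at higher levels, with 15 of 28 proliferation genes passing and none lower (median log2 ratio 2.11, percentile 100). Top2a, which untangles chromosomes in division, had 326 against 23.9 CPM (log2 ratio 3.31, 95% counting interval 3.23 to 3.39), and Mki67 had 206 against 18.2 CPM. 7 of 15 crest and progenitor genes were higher and 1, Phox2a, was lower (median log2 ratio 1.99, percentile 100), with Sox10 at 786 against 98 CPM, Ret at 374 against 55.7 CPM and Erbb3, a neuregulin receptor, at 502 against 24.9 CPM. Differentiated neuronal transcripts were lower, with 19 of 24 neurotransmitter and subtype genes passing (median log2 ratio -4.31, percentile 0), among them Gal with 289 against 2079 CPM and Vip with 20.2 against 456 CPM.

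Of the 18 pan-neuronal genes 7 were lower and 1, Map2 (2.64), was higher (median log2 ratio -0.96, percentile 0.47). Prph (-5.22), Nefl (-5.05) and Snap25 (-3.43) were lower, while Elavl4 had 207 against 162 CPM and did not pass. 9 of 20 cholesterol synthesis genes were higher (median log2 ratio 1.71, percentile 100), such as Dhcr7 with 187 against 17.6 CPM. 6 of 12 FGF and EGF response genes were higher (median log2 ratio 1.56, percentile 100), with Etv4 at 5.69 and Dusp4 at 3.40; the medium held both growth factors. 5 of 13 Notch pathway genes were higher (median log2 ratio 0.44, percentile 87), including Notch1 (3.24). Glial genes were 1 higher and 3 lower of 16 (median log2 ratio 0.12, percentile 73.4), and myelin genes 1 higher and 5 lower of 12 (median log2 ratio -0.76, percentile 11). Immediate early and dissociation stress genes were lower in 13 of 15 (median log2 ratio -4.45, percentile 0), with Fos at 167 against 3221 CPM. Primary and spheroid cells had no culture after the sort and neurospheres 10 days. For this list and the interferon response genes, recent dissociation and sorting therefore cannot be told apart from culture. That holds in each later comparison of neurospheres with primary or spheroid cells. 5 of 15 interferon genes were lower (median log2 ratio -1.46, percentile 0.07).

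Markers of several other cell types were at far lower levels in M1 neurospheres, including all 12 smooth muscle genes (median log2 ratio -8.02, percentile 0), 12 of 13 macrophage genes (median log2 ratio -4.11, percentile 0), 10 of 11 endothelial genes (median log2 ratio -4.79, percentile 0) and 9 of 10 epithelial genes (median log2 ratio -4.74, or -4.47 with members at 0 reads held at their bound, percentile 0.01). 6 of 7 mesothelial (median log2 ratio -4.02, percentile 0.01), 10 of 12 adipocyte (median log2 ratio -6.02, or -5.75 with members at 0 reads held at their bound, percentile 0), 9 of 9 lymphocyte (median log2 ratio -4.85, or -4.79 with members at 0 reads held at their bound, percentile 3.65) and 4 of 4 erythroid genes (median log2 ratio -10.7, percentile 0) were lower, as were 7 of 16 fibroblast and matrix genes (median log2 ratio -1.50, percentile 0.02). Only 3 of 6 mast cell genes were lower (median log2 ratio -2.40, percentile 5.45), and interstitial cell of Cajal genes were 1 higher and 2 lower of 8 (median log2 ratio -1.13, percentile 11.8). Myh11 had 6.01 against 2901 CPM, and Lyz2, a macrophage lysozyme that did not pass, had 1213 against 2843 CPM. All 10 genes with the lowest ratios were digestive enzymes or other acinar secretory genes (Zg16, Cela2a, Cpa1, Reg1, Ctrb1, Rnase1, Pnliprp1, Amy2b, Cel and Gp2), and Cela2a had 0.944 against 15480 CPM. Lrtm1, Pth2r, Dcc and Tecta led the highest with 0 reads in primary cells (at least 268-fold, 231-fold, 215-fold and 206-fold higher, respectively). They were followed by Olig1 (8.27), Slco4a1 (7.50), Mmp8 (7.0), Wnt16 (6.43), Lhfpl3 (6.41) and Ptprv (6.10). In all, 1016 genes were higher and 2522 lower among 15422, or 28.7% higher. Over genes at CPM 1 in a cultured tdTomato-positive library, 1016 were higher and 1403 lower, or 42% higher. With libraries scaled to total counts the split was 1713 higher and 2117 lower, or 44.7% higher.

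For adipose cells, 2-stage neurospheres were compared with primary cells. Here too the mix of cells could differ, since markers of immune, endothelial and adipocyte cells were lower in neurospheres. Myelin transcripts were at lower levels in 14 of 15 genes (median log2 ratio -5.41, percentile 0), with Mbp at 10.6 against 2093 CPM (log2 ratio -7.77, 95% counting interval -7.88 to -7.66) and Pmp22 at 8.13 against 2284 CPM. 9 of 16 glial genes were lower and 2 higher (median log2 ratio -2.79, percentile 0), with Gpr37l1 at 1.12 against 816 CPM and Gfra3 at 83.5 against 2836 CPM. The low-affinity nerve growth factor receptor Ngfr had 490.3 against 13.7 CPM (log2 ratio 5.01, 95% counting interval 4.92 to 5.11), and the crest and progenitor genes had 5 higher members of 13 and 1 lower, Sox8 (median log2 ratio 0.98, percentile 99.7). Sox10 had 632 against 377 CPM and Cdh19, a Schwann precursor cadherin, 977 against 719 CPM; neither passed.

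None of 28 proliferation genes passed (median log2 ratio 0.56, percentile 96). Pan-neuronal genes, 7 of them measured, were 2 higher and 1 lower (median log2 ratio 1.41, percentile 99.8), with Uchl1 at 502 against 8.96 CPM, Tubb3 at 209 against 44.5 CPM and Syp at 1.01 against 30.0 CPM; without the expression filter this median turned to -0.67. Neurotransmitter and subtype genes were 5 higher and 4 lower of 10 (median log2 ratio 1.33, percentile 99.9), with Penk at 132 against 9.48 CPM, Npy at 6.02 and Gad2 at 40.3 CPM in neurospheres, and this median turned to -0.36 without the filter. 5 of 13 FGF and EGF response genes were higher and 1 lower (median log2 ratio 0.77, percentile 97.8), and Notch pathway genes 3 higher and 3 lower of 11 (median log2 ratio 0.12, percentile 52.9), with Jag1 at 995 against 27.5 CPM. Interferon response genes were lower in 13 of 15 (median log2 ratio -5.08, percentile 0), with Isg15 at 4.48 against 58.5 CPM, and immediate early and stress genes in 12 of 15 (median log2 ratio -5.72, percentile 0), with Egr1 at 42.8 against 4698 CPM. None of 19 cholesterol synthesis genes passed (median log2 ratio -0.26, percentile 1.48).

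All measured macrophage (13; median log2 ratio -6.19, percentile 0), lymphocyte (12; median log2 ratio -9.80, or -9.51 with members at 0 reads held at their bound, percentile 0), endothelial (11; median log2 ratio -6.49, percentile 0.02) and adipocyte genes (10; median log2 ratio -6.43, or -5.96 with members at 0 reads held at their bound, percentile 0.07) were lower in neurospheres. 8 of 16 fibroblast and matrix genes were lower (median log2 ratio -2.35, percentile 0), such as Dcn with 11.3 against 993 CPM, while the matrix protein periostin (Postn) had 7036 against 3086 CPM and did not pass. 5 of 6 mast cell genes were lower and 1, Gata2, was higher (median log2 ratio -7.51, percentile 0.19), and melanocyte genes were 1 higher and 2 lower of 4 (median log2 ratio -3.0, percentile 44.2). Among the 10 highest, Hmga2, a chromatin protein of growing cells, Col10a1, Add2, Asgr1 and the peptide gene Ucn2 had 0 reads in primary cells (at least 2320-fold, 2270-fold, 1590-fold, 1090-fold and 637-fold higher, respectively). Fgf5 (10.64), Tmem179 (10.32) and the copies Prl2c2 (12.80) and Prl2c3 (10.94, interval 10.00 to 17.78) were also among them. The 10 lowest included immune genes, such as the chemokines Ccl5 (at least 15800-fold lower) and Ccl22 (-13.56), Ccr7 (-14.61, interval -18.66 to -13.76), Apol7c (-14.22), H2-M2 (-13.94) and Samsn1 (-12.69, interval -16.74 to -11.84). Sfrp5 (at least 13900-fold lower), Cd209f (at least 3650-fold lower), Rarres2 (-12.07) and Fcna (at least 2900-fold lower) were among the 10 lowest too. In all, 845 genes were higher and 3068 lower among 14773. Over genes at CPM 1 in a cultured tdTomato-positive library, 845 were higher and 1976 lower.

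The matching 2-stage contrast in the bowel, M2 neurospheres against primary cells, showed higher crest transcripts and lower neuronal ones. Since markers of other cell types were lower as well, a changed mix of cells cannot be told apart from changes within crest-derived cells. 8 of 15 crest and progenitor genes were higher and 1, Phox2a, was lower (median log2 ratio 2.01, percentile 100), with Ngfr at 365 against 5.88 CPM (log2 ratio 5.66, 95% counting interval 5.52 to 5.83) and Sox10 at 661 against 98 CPM. 11 of 18 pan-neuronal genes (median log2 ratio -2.26, percentile 0) and 18 of 24 neurotransmitter and subtype genes (median log2 ratio -6.08, percentile 0) were lower, with Snap25 at 6.34 against 417 CPM and Vip at 7.72 against 456 CPM. Gap43, a growth cone protein, and Map2 went the other way, with 2917 against 212 CPM for Gap43 and 157 against 20.7 CPM for Map2. The glial filament gene Gfap had 874 against 65.6 CPM (log2 ratio 3.45, 95% counting interval 3.40 to 3.5), and 4 of 16 glial genes were higher and 3 lower (median log2 ratio 0.22, percentile 62.6).

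7 of 28 proliferation genes (median log2 ratio 1.44, percentile 100), 6 of 20 cholesterol synthesis genes (median log2 ratio 1.47, percentile 100) and 5 of 13 FGF and EGF response genes (median log2 ratio 1.81, percentile 100) were higher, with Top2a at 3.10, Cyp51 at 2.52 and Etv4 at 5.44; Hbegf (-2.08) was a lower member of the last list. 9 of 15 immediate early genes (median log2 ratio -2.54, percentile 0) and 10 of 15 interferon genes (median log2 ratio -2.56, percentile 0.03) were lower. All 12 smooth muscle genes (median log2 ratio -10.1, percentile 0), all 7 mesothelial genes (median log2 ratio -10.6, percentile 0) and all 13 macrophage genes (median log2 ratio -7.43, percentile 0) were lower, as were 11 of 16 fibroblast and matrix genes (median log2 ratio -4.41, percentile 0), 5 of 7 interstitial cell of Cajal genes (median log2 ratio -5.14, or -4.74 with members at 0 reads held at their bound, percentile 0.505) and 9 of 11 endothelial genes (median log2 ratio -6.85, or -6.48 with members at 0 reads held at their bound, percentile 0). Myelin genes were 1 higher and 5 lower of 12 (median log2 ratio -0.66, percentile 21.3). Pth2r, Ucn2 and Lrtm1 led the highest genes with 0 reads in primary cells (at least 707-fold, 691-fold and 278-fold higher, respectively), with Olig1 (9.66) and Lhfpl3 (9.18). The 5 lowest were digestive enzyme and secretory genes of the pancreas, Cela2a (-14.34), Amy2b (-14.30, interval -18.46 to -13.56), Ctrb1 (-14.30), Zg16 (-13.96) and Cpa1 (-13.93). In all, 894 genes were higher and 3187 lower among 15189. Over genes at CPM 1 in a cultured tdTomato-positive library, 894 were higher and 2009 lower. With libraries scaled to total counts the split was 1262 higher and 2959 lower. The adipose and bowel culture ratios, from 4 separate libraries, correlated across 13895 genes at a Pearson r of 0.658 and a Spearman rho of 0.55, with 202 genes higher in both (42.2 for independent lists), 1657 lower in both (414) and 161 opposite (266). With a filter at CPM 5, 1141 genes passed in the same direction in place of 1859.

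M2 neurospheres were set against M1 neurospheres, which differ in the order of sorting and culture and also in culture time, with 10 days before and 10 after the sort for M2 and only 10 after it for M1. Markers of several non-neural lineages were lower in M2, with 6 of 6 mesothelial genes (median log2 ratio -6.73, percentile 0), 7 of 12 macrophage genes (median log2 ratio -2.40, percentile 0) and 7 of 13 fibroblast and matrix genes (median log2 ratio -2.59, percentile 0) passing. Lyz2 had 17.1 against 1213 CPM (log2 ratio -5.98, 95% counting interval -6.07 to -5.89), and the macrophage metalloelastase Mmp12 had 0.0919 against 293 CPM (log2 ratio -10.99, 95% counting interval -12.91 to -10.34). Here too a different mix of cells cannot be told apart from changes within crest-derived cells. None of 14 crest and progenitor genes passed (median log2 ratio 0.12, percentile 37.3), with Sox10 at 661 against 786 CPM and Ret at 274 against 374 CPM.

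Glial genes were 3 higher in M2, Apod (2.91), Gfra3 (2.39) and Gfap (2.06), and 1 lower, Scrg1 (-2.78), of 16 (median log2 ratio 0.81, percentile 100). Pan-neuronal genes were 5 lower and 1 higher, Gap43 (2.08), of 16 (median log2 ratio -1.13, percentile 0.01), and 5 of 14 neurotransmitter and subtype genes were lower (median log2 ratio -0.81, percentile 2.8). 4 of 6 interstitial cell of Cajal genes (median log2 ratio -3.18, percentile 0), 4 of 5 epithelial genes (median log2 ratio -6.49, or -6.11 with members at 0 reads held at their bound, percentile 0), 4 of 4 mast cell genes (median log2 ratio -4.77, or -4.57 with members at 0 reads held at their bound, percentile 0.23), 5 of 11 smooth muscle genes (median log2 ratio -1.36, percentile 1.31) and 4 of 7 Hox genes of groups 6 to 9 (median log2 ratio -2.07, percentile 10.5) were lower. Endothelial genes were 2 higher and 3 lower of 7 (median log2 ratio -0.91, percentile 38.4), and 2 of 5 adipocyte genes were lower (median log2 ratio -1.55, percentile 12.3). 4 of 16 hypoxia and glycolysis genes were higher and 1 lower (median log2 ratio 0.63, percentile 99.7), with Bnip3 at 255 against 37.8 CPM and Pdk1 at 74 against 15.7 CPM, and immediate early genes were 4 higher and 1 lower (median log2 ratio 0.64, percentile 99.7). None of 28 proliferation genes passed (median log2 ratio -0.50, percentile 0). The 5 highest genes were the glutamate receptor Grm5 (5.10), Ucn2 (4.75), Gpr50 (4.69), Cdh8 (4.55) and Fosb (4.49). After Mmp12, the lowest were Clec4e (-9.16, interval -13.32 to -8.42), the mesothelial genes Upk3b (at least 368-fold lower) and Lrrn4 (-8.50, interval -12.66 to -7.75), and Angptl7 (-7.64). In all, 170 genes were higher and 1039 lower among 14141; at CPM 5 the count was 617 in place of 1209.

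The further 10 days as purified cells were examined by comparing M2 neurospheres with the tdTomato-positive spheroid cells from which such cultures start. 14 of 15 interferon response genes were lower after this stage (median log2 ratio -3.48, percentile 0), with Ifit3 at 17.6 against 443 CPM (log2 ratio -4.76, 95% counting interval -4.85 to -4.68) and Usp18 at 5.93 against 132 CPM. Summed over this list, libraries taken straight from the sort had between 646.1 and 2793 CPM, and neurospheres between 151.8 and 444.1 CPM. Recent sorting therefore cannot be told apart from the further culture for these genes. Some neuronal transcripts were higher, with 4 of 13 pan-neuronal genes (median log2 ratio 1.33, percentile 100) and 5 of 12 neurotransmitter and subtype genes passing (median log2 ratio 1.08, percentile 100), the latter with 2 lower members. Elavl4 had 125 against 11.5 CPM (log2 ratio 3.32, 95% counting interval 3.22 to 3.44), Chrna3 had 60.4 against 2.31 CPM and Gal had 328 against 61.6 CPM. 2 crest and progenitor genes of 14 were higher, among them Ret with 274 against 22.3 CPM (median log2 ratio -0.13, percentile 28.3).

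9 of 14 fibroblast and matrix genes were lower (median log2 ratio -2.44, percentile 0), with Fn1 at 580.5 against 4266 CPM and Dcn at 11 against 157 CPM. 6 of 15 immediate early and dissociation stress genes were lower (median log2 ratio -1.78, percentile 0), with Egr1 at -2.95. The spheroid cells came straight from the sort, so for this list too recent sorting cannot be told apart from the further culture. Glial genes had 1 lower member of 16, Sostdc1 (median log2 ratio -0.13, percentile 39.4), and Gpr37l1 had 453 against 384 CPM. Myelin genes were 1 higher, Pmp22 (2.02), and 2 lower of 10 (median log2 ratio 0.66, percentile 99.5). No cholesterol synthesis gene of 20 passed (median log2 ratio 1.03, percentile 100), nor did any of 28 proliferation genes (median log2 ratio 0.39, percentile 100) or 11 macrophage genes (median log2 ratio -0.19, percentile 40.3). Notch pathway genes were 1 higher and 2 lower of 14 (median log2 ratio -0.71, percentile 0.48), with Hes1, a Notch target, at 34.4 against 239.9 CPM. Grm5 (7.74, interval 6.90 to 14.69), the kinase Camk1g (6.20), the neuronal connexin Gjd2 (5.94), Gpr22 (5.55) and Sh3gl2 (5.09) were the 5 highest genes. Pdgfb (-7.77, interval -11.93 to -7.02), the cytokine Il6 (-6.73), Clu (-6.04), the acute phase gene Saa3 (-5.80) and Thbs4 (-5.47) were the 5 lowest. In all, 413 genes were higher and 516 lower among 13432; at CPM 5 the count was 514 in place of 929.

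Finally, 10 days of culture as purified cells (M1) was compared with 10 days as a mixed spheroid (tdTomato-positive cells), which differ in when the sort took place. Neuronal transcripts were at higher levels in M1, with 12 of 16 pan-neuronal genes (median log2 ratio 3.39, percentile 100) and 9 of 15 neurotransmitter and subtype genes passing (median log2 ratio 2.58, percentile 100). The lower members of both lists were Gap43 (-2.27) and Gad2, which had 0 reads in M1. Elavl4 had 207 against 11.5 CPM (log2 ratio 3.88, 95% counting interval 3.77 to 3.99), and Snap25 had 53.1 against 2.01 CPM (log2 ratio 4.41, 95% counting interval 4.18 to 4.70). Interferon response genes were lower in 12 of 15 (median log2 ratio -2.49, percentile 0) and immediate early genes in 10 of 15 (median log2 ratio -2.90, percentile 0), with Ifit3 at 59 against 443 CPM and Fos at 167 against 1953 CPM. Markers of other cells were higher in M1, namely 8 of 12 macrophage (median log2 ratio 2.54, percentile 100) and 6 of 6 mesothelial genes (median log2 ratio 6.96, percentile 100). A different mix of cells, including neurons, therefore cannot be told apart from an effect of culture as purified cells.

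4 crest and progenitor genes of 14 were higher (median log2 ratio 0.055, percentile 94.8), including Ret (3.78), Sox8 (2.58) and Ednrb (2.10). Glial genes were 2 higher and 4 lower of 16 (median log2 ratio -0.85, percentile 0.08), the lower ones including Apod (-4.10), Gfap (-2.52) and Gfra3 (-2.18). 2 of 20 cholesterol synthesis genes were higher, among them Lss (median log2 ratio 1.36, percentile 100), and all 20 had ratios above 0. No proliferation gene of 28 passed (median log2 ratio 0.95, percentile 100), although all had ratios above 0. 4 of 6 interstitial cell of Cajal genes (median log2 ratio 2.30, percentile 100), 4 of 5 mast cell genes (median log2 ratio 5.11, or 4.58 with members at 0 reads held at their bound, percentile 99.3), 4 of 5 epithelial genes (median log2 ratio 5.46, percentile 99.9) and 4 of 11 smooth muscle genes (median log2 ratio 0.80, percentile 94.7) were higher. Fibroblast and matrix genes were 1 higher, Col1a2, and 2 lower, Fn1 and Postn (median log2 ratio 0.082, percentile 95.7). Lrrn4 (8.44, interval 7.63 to 12.53), Chgb (7.97, interval 7.13 to 14.92), Slc40a1 (7.67), Chdh (7.61, interval 6.79 to 11.70) and Upk1b (7.46, interval 6.64 to 11.55) were the 5 highest genes. Gad2 (at least 380-fold lower), Fosb (-7.76), Slco1a5 (-7.14), Ucn2 (-6.42) and Ly6a (-6.10) were the 5 lowest. In all, 1291 genes were higher and 446 lower among 14245; at CPM 5 the count was 1062 in place of 1737.

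**Figure D3:**
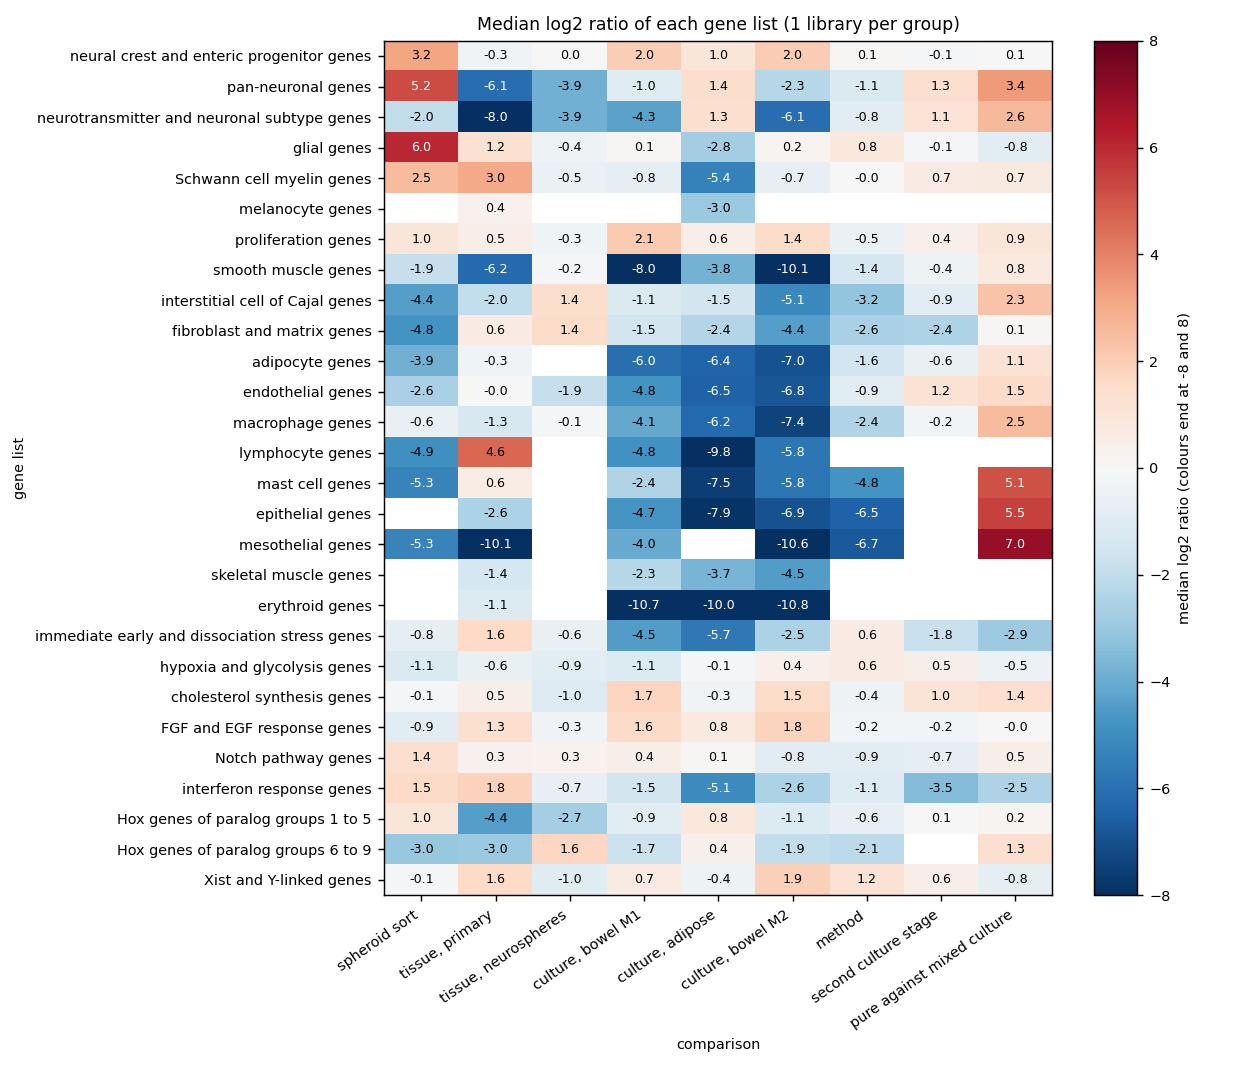
Median log2 ratio of each gene list (vertical axis) in each of the 9 comparisons (horizontal axis), with 1 library per group; red is higher in the first-named group of the comparison, blue lower, and blank cells had under 4 measured members. Smooth muscle medians lay between -8.02 and -10.1 in both bowel culture comparisons.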

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

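The tests of a mesenchymal source and of shared paralog reads were chosen only after the result was seen; that of a pancreatic source was set after the enzyme reads were seen but before the genes it uses were examined. The results below stand out because medians of a gene list pointed in opposite directions in a pair of like comparisons; these differences were not tested. The members measured differed between the contrasts, so medians over shared members are given as well. Pan-neuronal genes had a median log2 ratio of 1.41 in adipose culture and -2.26 in bowel M2 culture, a difference of 3.67, with 7 and 18 members measured; over the 7 in both they were 1.41 and -0.96. The first turned to -0.67 without the expression filter. Neurotransmitter and subtype genes had medians of 1.33 and -6.08 in the same contrasts, a difference of 7.41, with 10 and 24 members; over the 10 in both they were 1.33 and -2.97. The first turned to -0.36 without the filter. Interstitial cell of Cajal genes had a median of -1.97 for adipose against bowel in primary cells and 1.42 in neurospheres, a difference of -3.39, with 7 and 4 members (-1.92 and 1.42 over the 4 in both), and the second was -2.68 with M1 as the bowel library. Hox genes of groups 6 to 9 had medians of -3.0 and 1.63 in these tissue comparisons, a difference of -4.63, with 7 members in each (-2.35 and 1.2 over the 4 in both).

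The freshly sorted bowel library had 9.12% of its reads on acinar genes, led by Cela2a (15480 CPM), Cela1 (8642 CPM) and Prss2 (7585 CPM), and Hox genes of groups 6 to 9 above those of adipose cells. Reads shared between trypsin and elastase copies were argued against as the whole source of the enzyme reads, since 8 of 8 single-copy genes reached 10 CPM, the lowest of them Gp2 at 858 CPM. These 8 belong to the acinar list, which was written after its values were seen. The 10 CPM bar could therefore not fail, and only their levels bear on the question. Cells or free RNA of the pancreas may have been carried into the sort, as 9 of 12 further acinar genes were lower in adipose than in bowel primary cells and 0 higher (median log2 ratio -9.13), with Pdia2 at 0.89 against 484 CPM. Rab3d, with 76.6 against 69.5 CPM, did not pass, and Nr5a2 and Aqp8 were under 1 CPM in both libraries. 0 of the 12 are in a fixed list and 1 reached 1 CPM in a cultured bowel library. A clean tdTomato sort would remove such cells, and whether free RNA would stay was not tested. For the Hox genes, mesenchymal cells of the gut wall stay open as a source, because the values below could not decide it. The median log2 ratio of these genes was -3.02 in tdTomato-positive against tdTomato-negative spheroid cells, with Hoxc8 at 0.294 against 12.4 CPM. Summed over their lists, bowel primary cells had 1.06 times the Hox level of tdTomato-negative cells and 0.138 times their fibroblast and matrix level. The tdTomato-negative cells had been cultured for 10 days, so these ratios of fresh to cultured cells cannot weigh on the source. Between the primary libraries, the fibroblast and matrix level was 16210 CPM in adipose against 6995 CPM in bowel cells. Cells of the fat pads can hold these transcripts too, so this level cannot weigh on gut wall cells in the bowel library. Col3a1 had 8326 against 1644 CPM and Dcn 993 against 2308 CPM. Smooth muscle genes, which also belong to the gut wall, summed to 35140 CPM in bowel and 759.3 CPM in adipose primary cells, and to 473 CPM in tdTomato-negative cells. A difference between the tissues in the crest-derived cells themselves was not tested and stays open.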

How the results depend on the processing

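The choice of genes at 1 CPM in a cultured tdTomato-positive library was made after seeing the data, and the other alternatives before. No paired analysis was possible because all samples share replicate number 1 and each group holds 1 library, so that leaving out a replicate was not possible either. Of 69 counts of genes passing the size rule under an alternative, 45 lay within 1.5 times the main count, including each one under total counts, DESeq2 size factors and a prior count of 0.5. For the 9 comparisons (in the order spheroid sort, tissue in primary cells, tissue in neurospheres, culture of bowel M1, of adipose and of bowel M2 cells, method, second stage, pure against mixed), a 2-fold rule gave 4671, 5594, 4091, 7105, 6916, 7426, 3244, 2647 and 3598 genes, against 2664, 2882, 1884, 3538, 3913, 4081, 1209, 929 and 1737, since a looser rule passes more genes and a stricter one fewer. An 8-fold rule gave 1839 genes for tissue in primary cells, 1087 for tissue in neurospheres, 2065 for bowel M1, 591 for method, 377 for the second stage and 902 for pure against mixed. At CPM 5, where fewer genes were counted, these were 1909, 1216, 617, 514 and 1062 for the same comparisons without bowel M1, and 247 and 1141 genes passed alike in both tissue and both culture comparisons, against 479 and 1859. With no filter, where more genes were counted, 4365, 1924 and 1624 passed for tissue in primary cells, method and second stage. Over genes at 1 CPM in culture, 1808 passed for tissue in primary cells.

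Of 1117 list medians under an alternative, 1070 were the same, 37 moved and 10 reversed; none reversed with scaling or prior, and the cause was not tested. In adipose culture without a filter, the medians of pan-neuronal genes were -0.67 and of subtype genes -0.36. In the neurosphere tissue comparison, the interstitial cell of Cajal median was -0.57 without a filter and -2.68 against M1, and the fibroblast median was -0.31 against M1 and -0.030 against tdTomato-positive spheroid cells. Against M1, medians were 0.061 for immediate early, 0.095 for hypoxia and 0.34 for Xist and Y-linked genes, and that of proliferation genes was 0.0081 against the spheroid cells. Total counts moved the median of all genes by 0.24 (spheroid sort), -0.12 (tissue, neurospheres), 0.46 (bowel M1), 0.15 (adipose), 0.29 (bowel M2), -0.17 (method), 0.11 (second stage) and 0.29 (pure against mixed), and split bowel M1 into 1713 higher and 2117 lower genes against 1016 and 2522. With M1 as the bowel library, the neurosphere tissue comparison split into 555 higher and 2001 lower genes against 716 and 1168. A count near the main one did not mean the same genes. Of the main calls, 252 higher and 555 lower genes passed alike against both M1 and the spheroid cells. Depth limited ratios against 0 reads to bounds.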

Other observations

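The tests of unchanged carried-over neurons, of a lower crest cell share and of leaked reads were chosen only after the result was seen; those of mature dendritic cells and of neuronal differentiation were set after the immune and neuronal results were seen but before the further genes they use were examined. Some genes among the named ones had levels that did not follow tissue. Gad2, which makes GABA, had 40.3 CPM in adipose neurospheres, 18 in tdTomato-positive spheroid cells, 0.827 in M2 neurospheres and 0 reads in M1. Ucn2, a peptide of the corticotropin-releasing family, had 33 CPM in adipose neurospheres, 128 in tdTomato-positive spheroid cells, 43.8 in M2 and 1.79 in M1, with 0 reads in both primary libraries. Olig1, a transcription factor of oligodendrocyte precursors, had 56.6 CPM in M1 and 132 in M2 against 0.104 in bowel primary and 8.16 in adipose neurospheres. Thbs4 had 3939 CPM in tdTomato-negative cells, 29.1 in positive ones and 0.674 in M2.

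All pools were described as 2 females and 1 male, yet the sum of 4 Y-linked genes divided by Xist ranged from 0.548 in bowel primary and 0.618 in M1 cells to 5.35 in adipose primary and 5.43 in M2 cells, with 1.27, 1.52 and 2.09 in tdTomato-negative, adipose neurosphere and tdTomato-positive cells. The mix of mice may thus have differed between libraries, which was not tested. Differences between animals therefore cannot be told apart from those of tissue, culture or method. In the tissue comparison of primary cells, 1 of 5 Xist and Y-linked genes was higher, Uty (median log2 ratio 1.59, percentile 99.7), and in bowel M2 culture 2 of 5, Ddx3y and Uty (median log2 ratio 1.93, percentile 99.8).

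Immune transcripts were higher in the freshly sorted adipose library than in bowel cells, with 11 of 12 lymphocyte genes and Ccr7 among the named genes. A lower share of crest cells beside the same other cells was argued against, since lymphocyte and macrophage medians lay 5.92 log2 units apart and their interquartile ranges did not overlap, with the lower quartile of the first at 2.82 and the upper quartile of the second at -0.57. Reads leaked from another library of this series were argued against too, as 0 of 12 lymphocyte genes were higher in any other library. The same 12 genes define the pattern, so this count was largely set in advance and only their levels bear on the question. Summed, they had 641 CPM in adipose primary cells and at most 52.9 CPM in any other library. Mature dendritic cells carried into the sort may contribute, as 8 of 12 further marker genes were higher and 0 lower (median log2 ratio 3.52), just reaching the bound set for it; Tbc1d4 had 616 against 13.7 CPM, while the most abundant, Cd83, had 789 against 234 CPM and did not pass, 0 of the 12 are in a fixed list, 10 reached 1 CPM in bowel primary cells, and a strict tdTomato sort would remove such cells. A difference between the tissues in the crest-derived cells was not tested and stays open.

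Neuronal transcripts differed between tdTomato-positive spheroid cells and M2 neurospheres, with Elavl4 at 11.5 and 125 CPM. Unchanged mature neurons carried over from the primary cells were argued against as the whole source. Of 18 neuronal genes at 100 CPM or more in bowel primary cells, the 4 that passed as higher gained 12.8% (Gal), 29.1% (Syt1), 37.3% (Chrna3) and 70% (Elavl4) of their primary level. Such neurons would bring the other genes up alike, yet in 9 of 14 the whole M2 level lay under 12.8% of the primary one, with Snap25 at 1.52%, Prph at 0.671% and Stmn2 at 10.1%. The other 5 lay above that bound, at 29.6% (Syp), 46.1% (Penk), 62.7% (Uchl1), 136% (Tubb3) and more for Gap43. Syp and Penk gained 18.1% and 21.5% of their primary level, which did not speak against such neurons. Tubb3, Uchl1 and Gap43 fell instead, with gains of -55.9%, -32.5% and -83.5%. They had 427.8, 159.5 and 3094 CPM in the spheroid cells against 222.7, 167.5 and 211.8 CPM in primary cells. Snap25 had 2.01 against 417 CPM. Most of their reads there thus could not come from unchanged primary neurons, and their fall cannot weigh on such neurons. Neuronal differentiation in the purified culture may contribute, as 5 of 9 measured immature neuron genes were higher and 0 lower (median log2 ratio 2.58). Insm1 had 10.5 against 0.542 CPM and Celf3 22.7 against 2.09 CPM. The most abundant, Hes6, had 92.3 against 37.3 CPM and did not pass. In bowel primary cells, Insm1 and Celf3 had 0.433 and 10.1 CPM. The other genes that passed, Rtn1, Tlx2 and Tagln3, were higher in bowel primary cells than in M2. They had 394 against 3.87, 27 against 15.3 and 85 against 7.06 CPM. These genes therefore do not set new neurons apart from primary ones. 0 of this list's 12 genes are in a fixed list and 8 reached 1 CPM in bowel primary cells. A difference between the cultures behind these single libraries was not tested and stays open, and counting ELAVL4-stained cells at both stages would test it.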
